A study of Mus musculus with 5 samples.

How the data were processed

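Chromatin of sorted mTEClo from B6 mice was immunoprecipitated with an antibody to H3K36me3 by a protocol for small cell numbers, and sequenced as paired-end libraries, per the series' design text in the labels. The 5 samples are 2 ChIP libraries (series 1 and 2), 2 input libraries of series 1 and 1 input library of series 2. The labels say that the cells came from individual mice but do not tie a mouse to a library, so the spread between the 2 series may be biological, technical or both.

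The files analysed are 2 lists of broad peaks, 1 per ChIP library. Bowtie2, SAMtools and MACS2 on build mm10 are named in the submitters' processing notes, without versions, and the settings are not given in the sources used here. Per the peak names in the files, alignments were filtered and sorted, the series 1 ChIP was called against 2 input libraries together and the series 2 ChIP against 1. Peaks were called per ChIP library and not on pooled libraries. The authors deposited for each peak its chromosome, start, end, name and a whole-number score; its meaning is not stated. MACS2 usually writes 10 times the negative log10 of a q-value in that column, and the lowest score in both lists was 10. The files hold no fold enrichment, p-value or read count, so sequencing depth is unknown, the number of libraries limits precision, and binomial intervals on shares of peaks or genes cover counting error only. The scores run to 378 in series 1 and 483 in series 2. They were used to filter and rank peaks within a list; their correlation between lists and the mean over both series only describe these lists, which were called against different inputs and not normalized to each other. Read-level data of the input libraries were not used here.

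Gene spans and symbols came from a table of RefSeq genes on GRCm38.p6, whose chromosomes are those of mm10. It gives 1 span per gene, with no strand, exons or introns. For this reason the planned comparisons of coverage from the 5′ to the 3′ end and of exons with introns were not run, and neither were the alternatives that need fold enrichment or a q-value column; thresholds planned at a negative log10 q of 2 and 5 were set at scores of 20 and 50, and the correlation planned for fold enrichment used the score. Spans of 21883 protein-coding genes on chromosomes 1 to 19, X and Y were used. Where genes overlap, a peak counts for each, and strand cannot separate them.

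For each peak list the bases within genes and the bases shared with the other list were counted and compared with 1000 circular shifts, each with 1 random offset per chromosome between 3 Mb and the last annotated gene or peak. Such shifts keep widths and spacing but not mappability or gene density. A gene was called marked when at least 10% of its span lay under peaks in both series. Because only 4 genes met this rule, a second rule set beforehand, at least 1 bp, is the one described for gene lists; that choice was made after seeing the data. Genes hit in both series were compared with 1000 shuffles within 100 length classes. The share of each of 17 gene lists was compared with 10000 random lists matched on 10 length classes (two-sided permutation test over genes, smallest p = 0.0002), with Benjamini-Hochberg adjustment over the lists. The lists cover housekeeping and ribosomal protein genes, splicing factors, chromatin regulators, epithelial programmes, tissue-restricted antigen genes, receptor and zinc finger families, and markers of thymocytes, B cells, myeloid cells, fibroblasts, endothelium and erythroid cells. Lists, tests and alternatives were chosen before the data were examined, except those named as chosen later. The epithelial and tissue-restricted lists were compared by Fisher's exact test. Of the list members written down, 2 of the B cell list were not matched to a protein-coding gene, and 2 older symbols of the chromatin list named genes already in it, leaving 42.

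Genes named in the text followed a rule set beforehand: 20 fixed genes, of which 15 had no peak in either series; up to 4 best covered members of each list; the 10 genes with the highest mean score; the 5 widest peaks per series; and the 5 genes with the largest difference in covered share in each direction. Some genes of the tissue-restricted antigen list are not reported here by name. The list and score parts were applied to genes with at least 1 bp of a peak in both series. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. The tests were tried on simulated data. Among 100 circular shifts of the series 2 list, taken as independent lists, 2% were called at 0.05 for overlap. Over 21883 genes with series 1 marks set by length alone, 3.5% of 200 random lists of 60 genes and 6.5% of lists of 60 long genes were called. Lists with a chance of a mark raised 2.5-fold were called in 100% of 200 simulations. Shifts and marks set by length closely follow the rule that each test assumes, so these rates check the code. They do not show that the rule suits real peaks, and marks shared by overlapping genes were not simulated. Alternatives were stricter scores, merging of peaks within 3 kb, other overlap rules, autosomes only, peaks touching a coding gene only, the wider series 2 peaks only, all annotated genes, other gene rules, other matching, genes without a coding neighbour within 5 kb, and each series alone.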

Results

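H3K36me3, the trimethylation of lysine 36 on histone H3 that is laid down along transcribed gene bodies, was profiled by chromatin immunoprecipitation and sequencing in mTEClo of the mouse thymus. These are medullary thymic epithelial cells with low CD80, a part of the compartment that displays tissue-restricted self-antigens to developing T cells. The 5 samples were 2 ChIP libraries, called series 1 and series 2, and 3 input libraries made without antibody. Each ChIP library came with its own list of broad peaks called against input. Series 1 held 7231 peaks over 4.43 Mb, with a median width of 483 bp (interquartile range 332 to 842 bp). Series 2 held 10243 peaks over 3.38 Mb, with a median width of 222 bp (interquartile range 219 to 231 bp), and 65.6% of its peaks were at most 9 bp wider than its narrowest peak of 216 bp. The same width limit took in 1.92% of series 1 peaks. The lists carry no read counts, so the sequencing depth behind a peak is unknown and a gene without a peak was below detection in that library, which does not show that it lacked the mark. With 1 library per series and 2 in all, differences between the series have no replicate test.

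The first question was where the mark lay. Peaks of both series were concentrated in protein-coding genes. In series 1, 73.8% of peak bases fell between the annotated ends of a protein-coding gene, against 40.8% ± 0.856 (SD over 1000 circular shifts) when the same peaks were shifted along their chromosomes. In series 2 the share was 68.7%, against 40.7% ± 0.766 after shifting. Both excesses lay above all 1000 shifts (one-sided permutation test, p = 0.000999 in each series, the smallest that 1000 shifts can give). Sequence away from genes carried correspondingly fewer peak bases, 20.3% in series 1 and 23.2% in series 2, against shifted means of 45.6% and 45.9%. Genes that do not code for protein held 3.17% and 4.00% of peak bases where they overlapped no coding gene, below the shifted means of 8.34% and 8.27%.

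**Figure D1:**
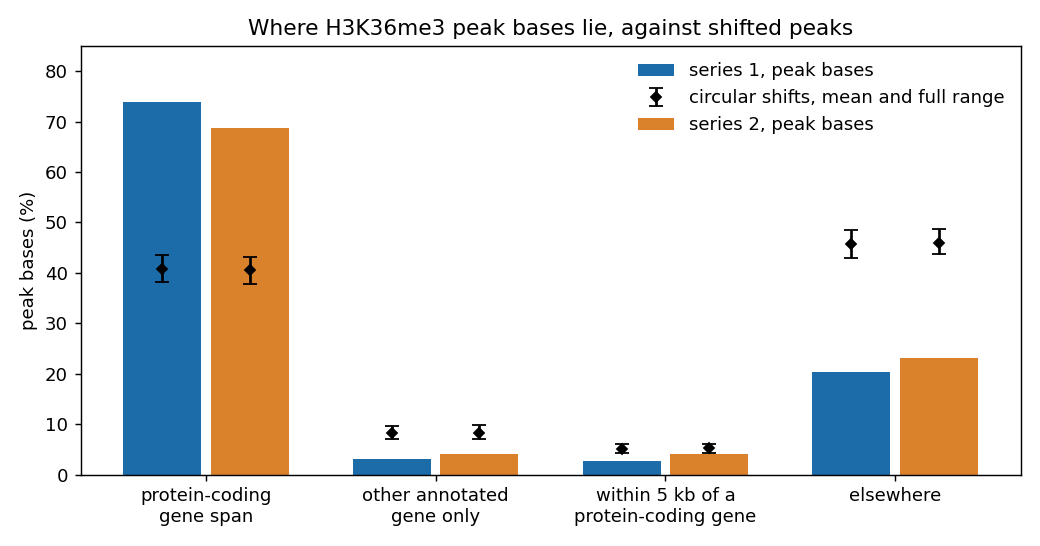
Percentage of peak bases (y axis) in 4 classes of sequence (x axis) for series 1 (blue bars) and series 2 (orange bars); black diamonds and whiskers give the mean and full range of 1000 circular shifts of the same peaks. Protein-coding gene spans hold 73.8% and 68.7% of peak bases, above every shift, and the class away from genes lies below every shift in both series.

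The second question was how far the peaks of the libraries coincide. The lists shared 127 kb, which is 2.86% of the bases of series 1 and 3.75% of those of series 2. Of the series 1 peaks, 360 (4.98%, exact binomial 95% interval 4.49 to 5.51%) touched a series 2 peak. Shifted lists shared 6.01 kb ± 1.44 (SD over 1000 shifts), so the shared length was 21.1 times that of shifted peaks (one-sided permutation test, p = 0.000999, the smallest possible). When series 2 peaks were instead placed at random within protein-coding genes, the ratio was 11.7. Of the shared series 1 peaks, 94.4% (91.6 to 96.6%) touched a protein-coding gene, against 71.2% of all series 1 peaks. The authors' peak score was weakly correlated between matched peaks. Over 359 pairs that matched one to one, Spearman's rho was 0.298 (95% bootstrap interval 0.201 to 0.390) and Pearson's r was 0.572, or 0.366 on the log10 scale, across peaks, which are not independent replicates. Over the 338 pairs left when only peaks touching a protein-coding gene were kept, rho was 0.271 and Pearson's r 0.212, so the higher r rests on the pairs outside genes.

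The libraries had a larger share of genes than of peaks in common, but these measures are unlike. A gene counts even where the peaks of the libraries lie at different places in it. Of 21883 protein-coding genes, 3570 (16.3%) held at least 1 bp of a peak in series 1, 4261 (19.5%) in series 2, and 1842 (8.42%) in both. Long genes were hit far more often than short ones: in the longest of 10 length classes, with a median length of 184.8 kb, 48.7% had a peak in series 1 and 61.3% in series 2, while in the shortest class the shares were 0.0457% and 0.183%. Independent lists would share 695 genes, and lists that are independent among genes of like length would share 1350. The 1842 observed exceeded that by 1.36-fold and lay above the highest of 1000 shuffles within length classes, which was 1421 (permutation test, p = 0.000999). Overlapping genes can share a peak but were shuffled singly. They are not independent draws, so the shuffles may spread too little and the p may be too small. With peaks of a score of at least 20 alone, 722 genes were hit in both series, and with at least 50 only 19.

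The rule fixed before the data were examined called a gene marked when at least 10% of its span lay under peaks in both series. Only 4 genes met it, and none of the 17 gene lists passed its test in both series with that rule. At 10% in either series, ribosomal protein genes (6 against 0.934 in random lists) and splicing factors (5 against 0.464) passed (permutation test, adjusted p = 0.0051 for each). In single series, ribosomal protein genes passed in neither, with 3 against 0.521 in series 1 and 3 against 0.422 in series 2 (permutation test, adjusted p = 0.275 and 0.138). Splicing factors passed in series 1 and not in series 2 (permutation test, adjusted p = 0.0068 and 0.138). The 4 genes marked in both series were Hnrnpa2b1, Sbds, Plrg1 and Rnf31, named after their values were seen. Hnrnpa2b1 encodes an RNA-binding protein of the hnRNP family that takes part in splicing. It lies on chromosome 6 from 51460434 to 51470048 (mm10) and had 22.3% and 13.1% of its span under peaks in series 1 and 2, 17.7% ± 6.51 (SD, n = 2). Sbds, a ribosome maturation factor on chromosome 5 from 130245732 to 130255530, was covered over 16.6% ± 9.01 (SD, n = 2). Plrg1, a component of the spliceosome-associated Prp19 complex on chromosome 3 from 83055538 to 83072291, reached 14.3% ± 4.84 (SD, n = 2), and Rnf31, a subunit of the linear ubiquitin ligase complex on chromosome 14 from 55591713 to 55603674, 11.3% ± 1.47 (SD, n = 2). All but Plrg1 have another coding gene within 1 kb. Taken singly, series 1 had 115 genes at 10% and series 2 had 51. The gene lists are therefore described by a second rule, also set beforehand, of at least 1 bp of a peak.

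**Figure D2:**
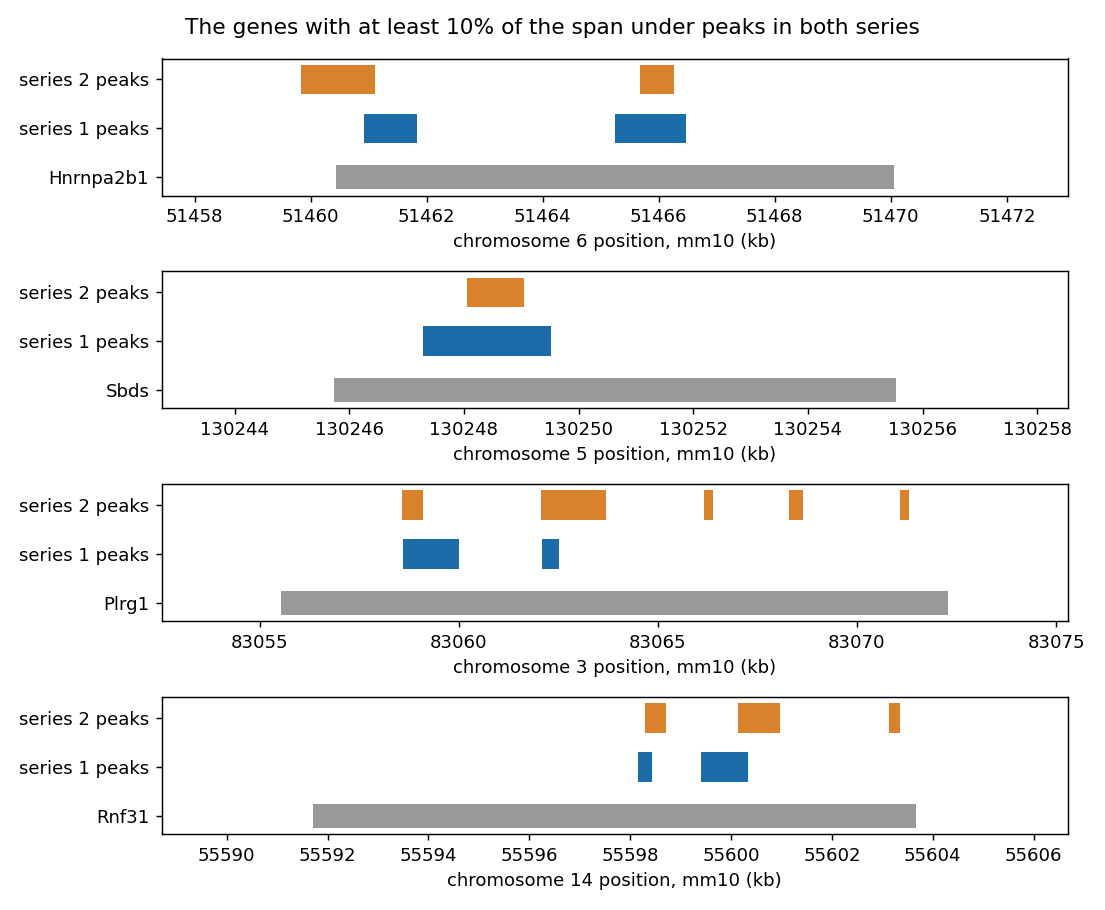
Position in kb on the mm10 assembly (x axis) of the 4 genes with at least 10% of their span under peaks in both series (grey bars) and of the peaks of series 1 (blue) and series 2 (orange) within 3 kb of them. Peaks of the 2 series overlap within each gene, and their number differs in Plrg1 (2 in series 1 and 5 in series 2) and Rnf31 (2 and 3) but not in Sbds (1 each) or Hnrnpa2b1 (2 each).

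Genes of RNA splicing factors carried peaks well above the level of genes of their length. Of 59 genes, 28 had a peak in series 1, 29 in series 2 and 16 in both, where length-matched random lists averaged 11.1, 12.9 and 5.33. The excess passed the permutation test over genes in each series and in both (adjusted p = 0.00113, 0.00113 and 0.0017, Benjamini-Hochberg over 17 lists). After Hnrnpa2b1, the members best covered in both were U2af2, the large subunit of the factor that binds the polypyrimidine tract, with 26.2% of its span in series 1 and 1.84% in series 2, then Srsf3 with 12.2% and 2.05% and Rbm5 with 8.86% and 4.04%. Raver2, which encodes an RNA-binding partner of the splicing repressor PTBP1, had no peak in either series. Raver1 had 1 in series 2 and Ptbp1 had 1 in each, both named after their values were seen. The excess in both series no longer passed with peaks of a score of at least 20 (6 genes against 2.00 in random lists) or among the 22 genes that have no coding neighbour within 5 kb (5 against 2.75).

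Genes of chromatin and H3K36 methylation regulators also carried more peaks than length-matched genes, with 15 of 42 hit in both series against 7.11 in random lists (permutation test, adjusted p = 0.0136). In series 1 there were 25 genes against 12.5 (permutation test, adjusted p = 0.00113), and in series 2 alone 20 against 15 did not pass (adjusted p = 0.366). Ep300, a histone acetyltransferase, was the best covered, with 9.25% and 5.24% of its span in series 1 and 2. Kmt2a, Supt5 and Chd4 followed, with means of 2.89% ± 2.13, 2.70% ± 2.07 and 2.70% ± 1.77 (SD, n = 2). Setd2, the enzyme that makes H3K36me3, held 1 peak in series 1 and 2 in series 2, over 1.28% and 0.519% of its span. Ribosomal protein genes, which are short, were hit in 5 of 82 cases in series 1 against 1.15 in random lists (permutation test, adjusted p = 0.0346) and in 4 in series 2 against 1.75 (adjusted p = 0.434), with only Rpl11 hit in both. In either series 8 were hit against 2.64 (permutation test, adjusted p = 0.0278). Among 35 housekeeping genes, 8 had a peak in series 1 (3.34 in random lists, permutation test, adjusted p = 0.051) and 5 in series 2 (3.77, adjusted p = 0.924). Polr2a and Gpi1 were hit in both, and Actb in neither. The chromatin excess in both series did not pass with a score of at least 20 (7 genes against 2.86) or among the 15 genes without a coding neighbour within 5 kb (5 against 2.40).

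The opposite held for tissue-restricted antigen genes, which encode proteins such as insulin, milk caseins, crystallins and myelin components whose expression outside the thymus is limited to few tissues. None of 114 had a peak in both series, against 5.86 in length-matched random lists (two-sided permutation test, adjusted p = 0.0136; exact 95% upper limit 3.18%). In series 1 there were 3 against 12.7 (permutation test, adjusted p = 0.0034), and in series 2 there were 2 against 15.3 (adjusted p = 0.00113). Syt1 was among those of series 1, and Sag and Tg were those of series 2, named after their values were seen. Ins2 had no peak in either. The count in both series stayed at 0 but did not pass where fewer were expected: 2.27 with peaks of a score of at least 20, 3.54 with only the wider series 2 peaks, and 2.97 among the 74 genes without a coding neighbour within 5 kb. Olfactory and vomeronasal receptor genes, which act in sensory neurons, had a peak in 1 of 1463 cases in series 1 and 10 in series 2, against 29.4 and 35.2, and in none in both, against 10.8 (permutation test, adjusted p = 0.00113, 0.00113 and 0.0017). With peaks of a score of at least 20 the count in both stayed at 0 against 3.59 and did not pass (permutation test, adjusted p = 0.288). Members of this family lie in clusters and resemble each other, so neighbouring genes are not independent draws and reads may map to several of them.

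Genes of the medullary epithelial programme were hit in 11 of 42 cases in series 1, 14 in series 2 and 7 in both, against 6.72, 8.03 and 3.31 in length-matched lists, and none of these excesses passed (permutation test, adjusted p = 0.165, 0.0809 and 0.193). Counted in either series, 18 stood against 11.3 (permutation test, adjusted p = 0.0369). The 7 include Krt5, the basal keratin of medullary epithelium on chromosome 15 from 101707069 to 101712905, with 1 peak in each series over 5.57% and 9.51% of its span. Lamb3, a laminin chain of the basement membrane, had means of 2.60% ± 0.929, Stat3 of 2.00% ± 0.343, and Itga6, an integrin chain of epithelial attachment, of 1.25% ± 1.12 (SD, n = 2). Trp63, the master regulator of stratified epithelium, had 2 peaks in series 1 and none in series 2. Relb, a subunit of the noncanonical NF-kappaB pathway, had 1 in series 2. Epcam, Krt14, Krt8, Foxn1, Ccl21a and Cd40 had none in either series. All 6 but Foxn1 are shorter than the median protein-coding gene of 17.2 kb.

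The direct contrast of the epithelial and tissue-restricted lists was made with the 1 bp rule as well. In both series together, 7 of 42 epithelial genes (16.7%) and 0 of 114 tissue-restricted genes held a peak (Fisher's exact test, two-sided, p = 6.93e-05). In series 1 the shares were 26.2% and 2.63% (Fisher's exact test, p = 3.47e-05), and in series 2 they were 33.3% and 1.75% (Fisher's exact test, p = 1.33e-07). This test does not match on length, and median lengths were 15.6 and 10.3 kb. With the 10% rule no gene of either list was marked in both series (Fisher's exact test, p = 1), so that rule cannot compare them.

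Gene lists of mature mTEC, of cortical TEC and of regulators of mimetic TEC subsets did not pass the test against genes of their length. Among 23 genes of mature mTEC, 4 had a peak in each series, against 2.64 and 3.11, and 7 had one in either series against 4.59 (permutation test, adjusted p = 0.37). Ciita, the transactivator of MHC class II genes, was hit in both. It overlaps Dexi, and a peak in the overlap counts for both. Aire and Fezf2, the regulators of tissue-restricted antigen expression in the mature cells, had no peak in either series, and Cd80, the marker by which the cells were sorted as low, had 1 in series 2. That peak covered 229 bp of Cd80 with a score of 12, near the lowest score of 10, and may be background. Among 18 cortical TEC genes, 2 and 4 had a peak in series 1 and 2, against 3.26 and 3.87, with Ly75 hit in both and Psmb11 and Enpep in neither. Among 25 regulators of mimetic TEC subsets, 3 and 2 were hit, against 2.66 and 3.22, with Hnf4g in both. Zinc finger protein genes were hit in 78 of 394 cases in series 1 and 80 in series 2, against 62.5 and 72.6 (permutation test, adjusted p = 0.0667 and 0.611), and Zfp330 was the best covered of them at 16.6% ± 12.5 (SD, n = 2).

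Among markers of other cells that a thymic sort could contain, thymocyte genes had fewer peaks than length-matched genes in each series, and the other lists did not pass in a single series. The thymocyte genes, 30 in number and with a median length of 26.2 kb, had no peak in series 1 against 6.71 in length-matched lists (permutation test, adjusted p = 0.0034) and 2 in series 2 against 7.99 (adjusted p = 0.0315). The 2 were Satb1 and Arpp21, named after their values were seen, and Ptprc and Cd3e had none. In both series together the thymocyte count was 0 against 3.66, which did not pass (permutation test, adjusted p = 0.102). Endothelial genes, with 1 and 3 of 19 hit against 4.61 and 5.67, fibroblast genes, with 2 and 4 of 22 against 4.56 and 5.47, myeloid and dendritic genes, with 2 and 4 of 23 against 3.41 and 4.09, B cell genes, with 4 of 13 in each against 2.73 and 3.40, and erythroid genes, with 1 of 13 in each against 1.18 and 1.44, did not pass in either series taken singly. B cell genes with a peak in either series numbered 7 of 13 against 4.56 (permutation test, adjusted p = 0.263). This share was larger than that of the medullary epithelial list, but so was the share in length-matched lists, 35.1% against 27.0%. Observed over expected was 1.53 for B cell and 1.59 for medullary epithelial genes, and no test compared the lists. Endothelial genes with a peak in either series numbered 3 against 7.57 (permutation test, adjusted p = 0.0438). Ebf1, Fbn1 and Flt1 were the members hit in both. P-values over genes describe these libraries, since genes are not replicates.

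**Figure D3:**
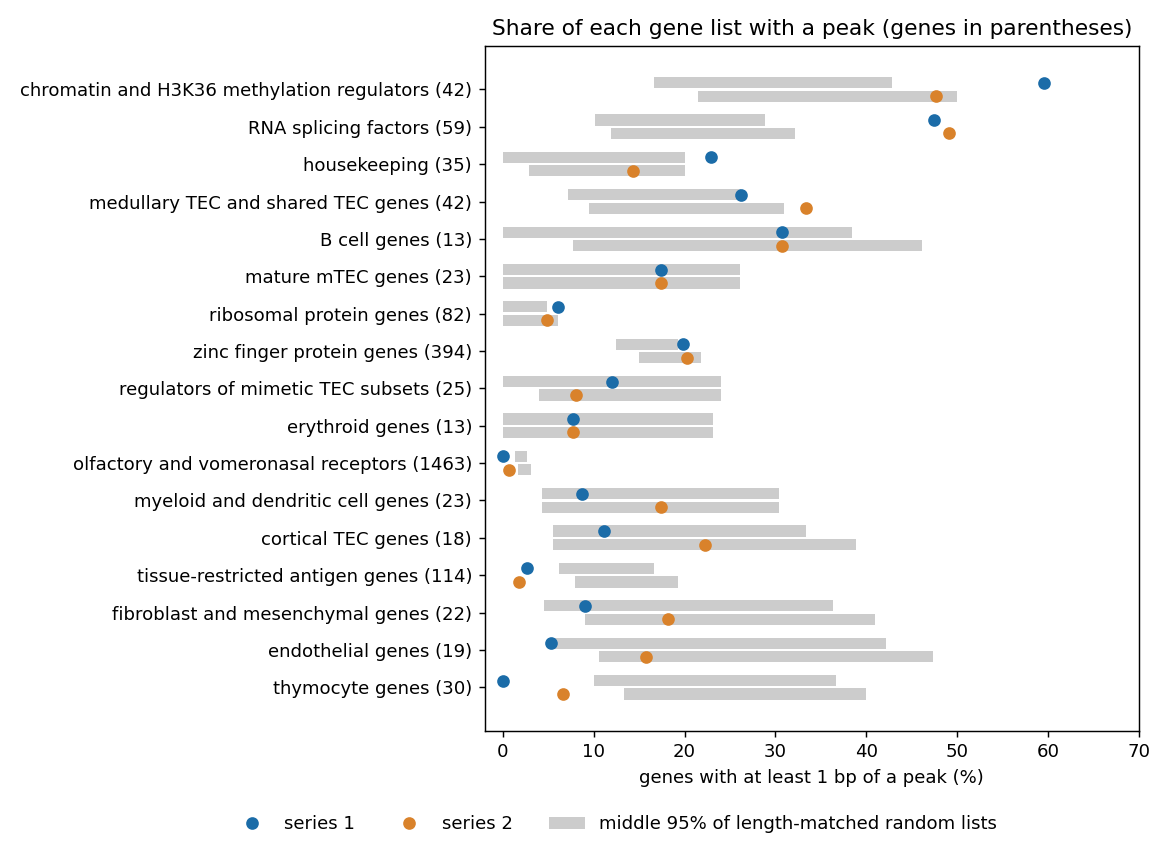
Percentage of genes with at least 1 bp of a peak (x axis) for each of 17 gene lists (y axis, number of genes in parentheses) in series 1 (blue) and series 2 (orange), with grey bars for the middle 95% of 10000 length-matched random lists. Splicing factors lie above the grey range in both series, at 47.5% and 49.2%, and tissue-restricted antigen, olfactory and thymocyte genes lie below it in both.

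The genes with the highest mean peak score over both series, among those with a peak in each, were Arhgap1, Krt5, Pafah1b1, Vps36, Ifnar1, Fxyd6, Rin3, Abi1, Myo9a and Itga3. The mean was often carried by 1 series: scores were 295 in series 1 and 50 in series 2 for Arhgap1, 104 and 76 for Krt5, 146 and 12 for Ifnar1, 138 and 12 for Abi1, and 38 and 111 for Myo9a. Medians over all peaks were 21 and 16, and the lowest score in each list was 10. Arhgap1, which encodes a GTPase-activating protein, had 1 peak in each series over 3.97% and 3.26% of its span. The widest peaks of series 1 lay in Atg4a, Brd8 and Zfp326, at 4230, 3875 and 3555 bp, followed by 1 of 3396 bp outside annotated genes on chromosome 14 and 1 of 3210 bp in Trim25. Those of series 2 were 3678 bp at the same place on chromosome 14, 2618 bp in Ddx6, 2603 bp in Anxa5, 2497 bp in Il20rb and 2411 bp outside genes on chromosome Y. Whether the peaks outside genes on chromosomes 14 and Y are repeats with excess copies was not examined, and they were not removed. Atg4a encodes an autophagy protease and Ddx6 an RNA helicase of messenger RNA decay.

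Coverage of single genes differed widely between the series. The largest differences among genes that reached 10% in series 1 only were Sap25 (47.6% of the span against 0), Rpl37a (37.6%), Ndufa3 (36.1%), Bet1l (26.1%) and Hsbp1 (24.5%), all without a peak in series 2. Those in series 2 only were Xbp1 (35.1%), a transcription factor of the unfolded protein response, Usp27x (33.7%), Srsf6 (31.7%), Tufm (26.1%) and Olfr853 (23.9%), all without a peak in series 1. All 10 are under 6 kb long, and each has 1 library on either side, so no difference of this kind can be tested. Sap25, Ndufa3, Bet1l and Tufm have another coding gene within 1 kb, to which such a peak may belong.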

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

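Tests under the 1 bp rule, with the wider series 2 peaks alone, with peaks touching genes alone or with genes hit in either series were chosen after the data were seen, except the gene-list and gene counts at 1 bp themselves. The excess of peak bases in protein-coding genes and of bases shared by the series kept direction and significance under every alternative run, with 68.7 to 76.2% of bases in genes and 11.7-fold to 1979-fold shared length or peaks, the last at a score of at least 50, where 10914 bases were shared by 15 series 1 peaks and 30.7% of them by peaks touching a coding gene (1353-fold for these). The rank correlation of matched scores moved to 0.462 with reciprocal 50% overlap. The number of genes marked in both series was 4 by the 10% rule, 1842 with 1 bp, 0 with 25% of the span, 0 at a score of at least 50, 7 with peaks within 3 kb merged, and 51 to 115 in a single series. With the 1 bp rule, 1842 genes fell to 722 at a score of at least 20, 19 at 50 and 1098 with the wider series 2 peaks, and single series gave 3570 to 4261. Splicing factors (27.1% against 1.69%) and chromatin regulators (35.7% against 0%) were called with 1 bp and not with 10%. So were tissue-restricted antigen genes (0% of 114) and olfactory receptors (0% of 1463). For these antigen and receptor genes the 10% rule could not call a shortfall, since random lists averaged 0.033 and 0.0607 genes. Splicing factors reached 3.39 to 6.78% with 10% in single series and were called in series 1. Starting from the 1 bp rule, a score of at least 20 ended the calls for splicing factors (10.2%), chromatin regulators (16.7%), tissue-restricted antigen genes (0%) and olfactory receptors (0%), and so did a score of at least 50 (1.69%, 0%, 0% and 0%), where 4033 and 3660, or 453 and 254, peaks were left. Restricting to genes without a coding neighbour within 5 kb ended the calls for splicing factors (22.7% of 22 genes), chromatin regulators (33.3% of 15) and tissue-restricted antigen genes (0% of 74), with fewer genes tested. Both score limits removed most series 2 peaks over 500 bp. Keeping only the wider series 2 peaks ended the call for tissue-restricted antigen genes (0%, permutation test, adjusted p = 0.151). In single series the chromatin share was 47.6 to 59.5% and uncalled in series 2, thymocyte genes were called in both (0 to 6.67%), ribosomal protein genes (4.88 to 6.10%) were called in series 1, and lists with 1 gene hit in both series changed sign without a call: B cell (30.8% in each) and mature mTEC genes (17.4% in each), mimetic regulators in series 1 (12%) and cortical genes in series 2 (22.2%). These changes rest on small differences. In both series, B cell genes stood at 1 against 1.59 in random lists, mature mTEC genes at 1 against 1.145 and mimetic regulators at 1 against 1.32. Cortical genes in series 2 stood at 4 against 3.87. Zinc finger genes changed sign without a call at a score of at least 20 (2.28%). With Fisher's exact test unmatched for length, housekeeping (5.71%) and zinc finger genes (8.12%) did so too, and ribosomal genes were called in the opposite direction, as fewer than other genes (1.22%, adjusted p = 0.049). The gap between epithelial and tissue-restricted genes was 0 percentage points by the 10% rule, with no marked gene in either list. It passed the threshold with 1 bp at 16.7, at 38.5 with 1 bp in either series, at 16.7 with merged peaks, at 16 without near neighbours and at 23.6 to 31.6 in single series, but not with a score of at least 50 (2.38). Alternatives on fold enrichment, on coverage along the gene body and on exons against introns were not run, for lack of fold values, strand and exons here, and the score was the one measure for the correlation. Where no cause is named, the cause was not tested. No paired analysis was possible because the input libraries that share series numbers with the ChIP libraries have no values of their own in the peak lists. Unknown depth limits every statement about genes without a peak.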

Other observations

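The tests in this part were chosen after the peak lists were seen, and that of narrow peaks against shifts after its result was seen. Genes were grouped by a shared symbol stem, leaving out the stems Olfr, Vmn, Zfp, Rpl and Rps, whose families the gene lists cover. Among 252 such groups (10 to 500 genes each), the genes named Eif, which are mostly translation initiation factors but include kinases of eIF2 such as Eif2ak2 and Eif2ak4, were the group with a called excess of peaks. In either series 27 of 56 held a peak, against 14.1 in length-matched random lists (permutation test, adjusted p = 0.0252), with 17 in series 1, 21 in series 2 and 11 in both, Eif3a and Eif5b among them. RNA helicases of the DEAH group (Dhx) had 12 of 16 against 5.78 and the spliceosome genes named Prpf 9 of 13 against 3.70, and ubiquitin-specific proteases (Usp) had 34 of 56 against 23.3, with adjusted p of 0.0728, 0.101 and 0.0728, which did not pass. At the other end, 0 of 12 Pcdhga protocadherin genes held a peak against 8.24 (permutation test, adjusted p = 0.0252). These genes overlap in 1 cluster on 1 chromosome, so this is 1 locus and not 12 draws. The 12 Pcdha genes, which likewise overlap on 1 chromosome, all held a peak in both series, against 4.12 in both and 9.13 in either (permutation test for either series, adjusted p = 0.441). Phospholipase genes (Pla) had 0 of 21 against 6.49 and cytochrome P450 genes (Cyp) 14 of 99 against 26.5, with adjusted p of 0.063 and 0.0806. Before adjustment, Eif and Pcdhga tied at the smallest p that the random lists can give (permutation test, p = 0.0002). At that floor a single group among 252 would not have passed 0.05 after adjustment. The Eif call therefore rests on the tie with the Pcdhga locus, and the Eif genes alone would not have been called.

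In genes of at least 5 kb without a coding neighbour within 5 kb, peak bases were compared from the ends to the middle. Each gene's shares were averaged over genes with a peak, so every gene weighs the same. With both ends folded together into 10 equal steps, an even spread gives 10%. The outermost step held a mean of 9.19% of a gene's peak bases in series 1 (95% bootstrap interval over 1729 genes 8.05 to 10.5%), an interval that includes an even spread. In series 2 it held 8.17% (7.31 to 9.28% over 2075 genes), below an even spread. The innermost held means of 10.4% and 10.3%. The gene table has no strand, so the 5′ and 3′ ends were not separated.

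Among the peaks shared by both series, 17 of 360 lay outside any annotated gene, and they include the top score of each list. A peak on chromosome 2 from 98666726 to 98667297 scored 378 in series 1 and 483 in series 2. Peaks on chromosome Y at 90737525 to 90738730 and 90811297 to 90813764 scored 186 and 158 in series 1 and 242 and 138 in series 2, and several lay in the first part of chromosome 9, such as 3025125 to 3027146 with 35 and 85. No read-level data were used to see whether these are repeats with excess copies.

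The first pattern is that the narrow peaks of series 2, 6716 of 10243 that were at most 9 bp wider than its narrowest peak of 216 bp, touched a protein-coding gene in 56.1% of cases (exact interval 54.9 to 57.3%) and wider ones in 74.6% (73.1 to 76.0%). Background calls placed without regard to genes are argued against as the whole source, since the 56.1% lies above the highest of 1000 shifts (42.5%). The shifts do not keep mappability, so they cannot decide about background that follows mappable sequence. Lower peak score leaves little to explain, since a narrow peak scored below a wider one in 52.2% of pairs (95% bootstrap interval 51.1 to 53.4%, with ties split evenly; medians 16 and 16), and weighting to equal scores could therefore move the gap little, from 18.5 to 18.1 percentage points (16.04 to 20.18). That part of them is background is consistent with their nearness to series 1: 4.71% (4.21 to 5.24%) lay within 3 kb of a series 1 peak, against 14.4% (13.3 to 15.6%) of wider ones. The single input of series 2, a difference in depth and a difference between the mice remain open, and no biological explanation was tested.

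The second pattern is the X chromosome, which held 2.13% of peaks in series 1 (exact interval 1.81 to 2.49%) and 4.03% in series 2 (3.66 to 4.43%). Minimum-width peaks are argued against as the whole cause, because wider series 2 peaks still had an X share of 3.40% (2.83 to 4.06%). Within genes there were 1.47 peaks per Mb of gene on X and 5.17 on autosomes in series 1, and 3.85 and 6.32 in series 2, and outside genes 0.713 and 1.40 peaks per Mb in series 1 and 1.94 and 2.54 in series 2, so X was higher in series 2 in both kinds of sequence. The sex of the mice is not in the labels and stays open, as does depth.

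The third pattern is the rarity of peaks in tissue-restricted antigen genes. Peak-poor neighbourhoods are argued against as the cause: with random lists matched also on the peak bases within 500 kb outside the gene, 5 genes with a peak in either series stood against 22.8, a ratio of 0.219 (permutation test, p = 0.0002, the smallest that 10000 lists can give). The excess of genes hit in both series likewise stayed at 1.37-fold over shuffles within length and neighbourhood classes (1842 against 1346, highest shuffle 1413), which argues against peak-rich neighbourhoods as its cause. A candidate explanation for the rarity in tissue-restricted antigen genes is that few mTEClo transcribe any one of these genes, which peak lists of pooled cells cannot test. Mappability and GC content were not tested, and remain open for both the rarity and the excess.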
